A study of Vibrio hepatarius
Ruegeria pomeroyi DSS-3
Thalassospira sp. HF15 and Vibrio hepatarius
Ruegeria pomeroyi DSS-3 and Vibrio hepatarius
Thalassospira sp. HF15 with 40 samples.

How the data were processed

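RNA of 3 marine bacteria was sequenced from 40 cultures or pools in 10 groups of 4: pooled monocultures, the pairs RV, RT and VT, and the trio RVT, each at time points P4 and P8. Per the labels' protocols, RNA came from filters, ribosomal RNA was depleted, and stranded libraries were sequenced as single 75-base reads on an Illumina NextSeq. The labels do not say whether the 4 replicates of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Per the submitters' processing notes, STAR 2.6.1c and HTSeq were used, and the genome builds are not given in the sources used here.

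The deposited tables hold raw counts of reads per gene, 1 table per species and time point, with genes named by locus tag and no symbol or product. Several tables repeat others: every value that 2 tables share was identical (0 cells different). The authors also deposited tables with 3 of the 4 replicates for R and V at P8, which served only as an alternative. The P4 table of V ends in 10 rows with no gene name, filled in 12 of its columns. These hold 38.7% to 67.9% of those columns' sums and were left out. In the 4 columns of RV_P4 a foot row holds a share from 0 to 1, so that the deposited unit of these columns is other than counts as a whole, and the remaining values were read as counts. Samples were grouped by their titles, and columns were matched to samples by name.

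Library size was the sum over 1 species' genes, so that a change in a species' share of the community is not read as a change in each gene. Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM normalization, glmQLFit and glmQLFTest over the 4 groups of a species at a time point, and Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change over the square root of the F statistic. The difference between time points was an interaction term over all groups of a species. CPM values are TMM-normalized values scaled to the library size of that species, given as mean ± SD over 4 libraries. Shares and log2 ratios of species' reads were compared by 2-sided exact permutation tests over libraries. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry (limma 3.58.1). Since 1 list could be tested per comparison, its p and its adjusted p over lists are the same, and neither is adjusted over the comparisons. Intervals and floors (3 reads) cover counting error only. The shift of a library is the projection of its log2 CPM (prior count 2), less the mono mean, on a set of log2 fold changes. These are of the genes called in the pair with V at the other time point, limited to 5 in size. The shift is scaled to 1 for these limited changes. A library's own changes were not limited, so its shift is not an exact fraction of the full change and can pass 1.

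Before the data were examined, 28 gene lists, the comparisons, the alternatives and a rule for naming genes were fixed. With no symbols or products in the files, 27 lists matched 0 tags. The list for ectoine matched 12 tags of R through their numbers, SPO1137 to SPO1148, which were written down from general knowledge of this strain. The rule for named genes was the largest log2 fold changes with adjusted p under 0.05, a mean of at least 20 CPM in the higher group and no overlap between the groups' libraries, and, since no table pairs tags with products, at most 2 tags that rose and 2 that fell per comparison. They are given for the comparisons with monoculture and identified by tag alone. Genes that share reads with a near-identical copy in the same or another genome are uncertain, since how multiply mapped reads were treated is not given in the sources used here.

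Depth per library and species ranged from 54603 to 16480659 reads, and the floor of 3 reads stood at 54.9 CPM in the shallowest library of R and at 0.182 CPM in the deepest of T. On simulated data with 200 changed genes, the test recovered 80.3% of 4-fold changes for T in VT_P4, 95.5% for R in RV_P4, 90.9% for R in RV_P8, 59.1% for V in VT_P4 and 95.5% for V in RVT_P8, and 2-fold changes at 19.4%, 44.8%, 55.2%, 0% and 56.7%. False calls made up 2.88% to 7.69% of the calls. The simulated counts used the spread that the test itself had estimated, shared by all groups, and 1 mean per gene outside the changed genes. They therefore do not show the rate of false calls where most genes change or where groups differ in spread. No 2 libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 1.39 over 144 pairs).

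Alternatives were DESeq2 1.42.0 with its Wald test, DESeq2 size factors in edgeR, no filter on low counts, the replicate number as a block, the compared groups alone, thinning to equal depth, the top 1 percent of genes left out, the authors' 3-replicate tables, and each library left out. Library size alone without composition scaling was added after the data were seen, as were the shift of each library and a camera test of the tags with prefix SPOA.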

Results

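The series measured the mRNA of a synthetic community of 3 marine bacteria grown on a medium with 1.25 mM ectoine, a compatible solute that many marine bacteria make against salt stress and that others take up as food. The species were Ruegeria pomeroyi DSS-3 (here R), Vibrio hepatarius HF70 (V) and Thalassospira sp. HF15 (T). Each was grown alone, in the pairs RV, RT and VT, and in the trio RVT, and each condition was sampled at the time points P4 and P8, whose unit the labels do not give. This made 10 groups of 4 libraries, 40 libraries in all. The single-species cultures were pooled before library preparation, so a monoculture library (mono) holds reads of all 3 species that had grown apart. Reads counted for R genes ranged from 54603 to 4092857 per library over 4279 locus tags, for V from 106135 to 4934066 over 4416 tags, and for T from 1321264 to 16480659 over 3945 tags. The lowest totals were those of R in RV_P8 (69826 to 113622) and RVT_P8 (54603 to 260526) and of V in VT_P4 (106135 to 167737).

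In the mixed cultures with T, T held most of the assigned reads of each library except VT_P8 replicate 3, and in RV libraries V did. In RV, V held 87.2% ± 1.29 of the reads at P4 and 93.6% ± 1.98 at P8 (SD, n = 4 each). In RT, T held 90.6% ± 2.02 at P4 and 87.9% ± 4.88 at P8, and in VT, V held 3.58% ± 0.956 at P4 and 22.6% ± 19.0 at P8 (SD, n = 4 each). In the trio, T held 91.3% ± 1.06 at P4 and 86.9% ± 11.03 at P8, V held 6.40% ± 0.912 and 11.99% ± 11.1, and R held 2.32% ± 0.413 and 1.07% ± 0.285 (SD, n = 4 each). VT_P8 replicate 3, with 50.7% of reads from V, and RVT_P8 replicate 3, with 28.3%, gave the wide spread of the P8 values. Between time points, the share of V was higher at P8 in RV and in VT and the share of R in the trio was lower, each with p = 0.0286, the smallest a 2-sided exact permutation test of 4 against 4 libraries can give, and adjusted p = 0.0571 over the 6 shares, which misses 0.05. The other 3 share differences had exact permutation p from 0.457 to 0.8.

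The balance between 2 species differed when all 3 were present. The log2 ratio of T to R reads was higher in RVT than in RT by 2.02 at P4 and by 3.43 at P8, in 4 of 4 libraries each time. At P4 the log2 ratio of V to R reads differed by −1.31 between RVT and RV, lower in RVT in 4 of 4 libraries, and that of V to T reads was 0.94 higher in RVT than in VT, in 4 of 4 libraries. Each of these 4 differences had exact permutation p = 0.0286 and adjusted p = 0.0429 over the 6 ratios tested, and with medians in place of means each had p = 0.0571, which misses 0.05. At P8 the ratios of V to R and of V to T did not differ by the exact permutation test (p = 0.314 each). These are shares of reads, not of cells.

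**Figure D1:**
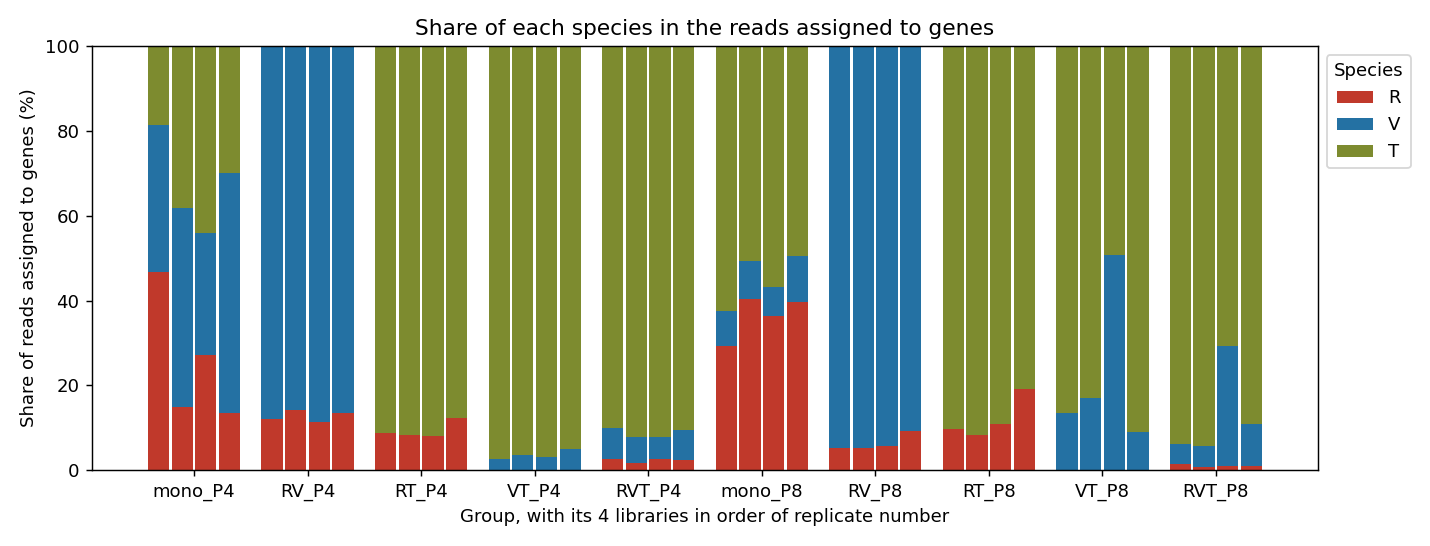
Share of the reads assigned to genes (%) held by R, V and T in each of the 40 libraries, 4 bars per group in order of replicate number. In the pairs, RV libraries were mostly V, and RT and VT libraries mostly T, except VT_P8 replicate 3, where V held 50.7%.

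In R at P4, more genes changed in the groups with V than beside T alone. Of 3525 genes tested, 1293 rose and 1375 fell in RV_P4 against mono_P4, 15 rose and 12 fell in RT_P4, and 1230 rose and 1013 fell in RVT_P4 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The RT_P4 count of 27 was 85 with the DESeq2 Wald test, 290 with the 2 compared groups alone in the fit and 5 after thinning to equal depth. With the 2 compared groups alone, 2951 genes changed in RV_P4 and 1572 in RVT_P4, the second not a majority of the genes tested. The 12 locus tags SPO1137 to SPO1148, the block that holds this strain's known genes for ectoine uptake and breakdown, fell together beside V. Their summed level was 7915 ± 297 CPM in mono_P4, 6901 ± 278 in RT_P4, 1114 ± 629 in RV_P4 and 2212 ± 1861 in RVT_P4 (SD, n = 4 each). All 12 fell in RV_P4 (median log2 fold change −3.27), none passed the test in RT_P4 (median −0.14), and 11 fell in RVT_P4 (median −1.55), with the counts 12, 0 and 11 when adjusted over the list alone. The block stood below the other genes in RV_P4 (camera p = 0.00144) and RVT_P4 (p = 0.000509) with a preset correlation of 0.01. It did not with the estimated correlation of its tags, 0.840 and 0.782 (p = 0.314 and p = 0.259). With fry, which does not set the block against other genes, p was 0.00036 in RV_P4, 0.0029 in RVT_P4 and 0.741 in RT_P4. RVT_P4 replicates 1 and 3 kept 4321 and 3235 CPM of the block, against 622 and 671 in replicates 2 and 4.

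Among single tags of R at P4, SPO0930 was 130-fold higher in RV_P4 (97.3 ± 40.4 CPM against 0.491 ± 0.595; adjusted p = 1.13e-07, edgeR) and SPO0054 120-fold higher (1114 ± 359 against 9.46 ± 2.05; adjusted p = 3.39e-07). SPO3366 fell by 4.94 on the log2 scale (SE 0.49), from 9387 ± 2738 CPM in mono_P4 to 306 ± 95.1 in RV_P4, and SPO2195 had a log2 fold change of −4.13 (SE 0.83), or −5.69 without RV_P4 replicate 4. In RT_P4, SPO3498 rose from 25.7 ± 6.34 to 219 ± 34.6 CPM and SPOA0189 from 21.3 ± 7.12 to 163 ± 36.1. After thinning to equal depth both had adjusted p = 0.0667, the highest over their alternatives that keep all libraries. The neighbours SPO1017 and SPO1018 fell in RT_P4, with log2 fold changes of −2.66 (SE 0.59) and −2.45 (SE 0.47). SPO1017 missed 0.05 under 6 alternatives, with adjusted p from 0.0633 with the top 1 percent of genes left out to 0.134 after thinning, and in 7 of 8 fits without 1 library. SPO1018 missed it in 3 of these 8 fits (adjusted p up to 0.122). In RVT_P4, SPO2192 rose from 13.0 ± 3.70 to 4690 ± 5230 CPM and SPOA0407 from 25.2 ± 4.62 to 2502 ± 2768, with adjusted p of 3.83e-05 and 1.04e-05 in edgeR. SPO1172 and SPO1177 fell in RVT_P4, with log2 fold changes of −3.58 (SE 0.53) and −3.56 (SE 0.82). SPO1177 was at −2.498 without mono_P4 replicate 1 and at −4.71 without RVT_P4 replicate 1, and without RVT_P4 replicate 2 the log2 fold changes of SPO2192 and SPOA0407 were 7.52 and 5.40 in place of 8.48 and 6.63. The RT_P4 count was 9, 14, 8 and 12 without RT_P4 replicates 1 to 4 and 16, 15 and 12 without mono_P4 replicates 1 to 3. Library size alone, without composition scaling, gave an RVT_P4 split of 930 up and 1330 down.

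In R at P8, 615 genes rose and 652 fell in RV_P8 against mono_P8 of 3330 tested, 308 rose and 260 fell in RT_P8, and 865 rose and 944 fell in RVT_P8 (edgeR, adjusted p under 0.05). The RV_P8 libraries did not stand together along the RV change seen at P4. On that scale 0 is the mono_P8 mean and 1 the change with log2 fold changes limited to 5. Replicates 2 and 3 were at 0.19 and 0.24, and replicates 1 and 4 at 0.55 and 0.60. The ectoine block fell again beside V: its summed level was 6805 ± 220 CPM in mono_P8, 5911 ± 188 in RT_P8, 757 ± 209 in RV_P8 and 453 ± 193 in RVT_P8 (SD, n = 4 each), 8.98-fold below mono in RV_P8 and 15.0-fold below in RVT_P8. Of its 12 tags, 11 fell in RV_P8, 5 in RT_P8 and 12 in RVT_P8, the same counts as when adjusted over the list alone. The exception in RV_P8 was SPO1140, at 422 ± 133 CPM against 403 ± 44.1 in mono_P8 and 112 ± 46.8 in RVT_P8. This 1 tag held most of the RV_P8 sum, so the folds of the sums do not rank RV_P8 and RVT_P8 for the rest of the block. The sums rest on 30 to 55 block reads per library in RV_P8 and 17 to 161 in RVT_P8. The block's median log2 fold change was −5.31 in RV_P8, or −4.72 with the 2 tags that had no read placed at a floor of 3 reads over the group, −4.17 in RVT_P8, the same with its 1 tag without a read at that floor, and −0.32 in RT_P8. The camera p was 5.24e-14 in RV_P8, 8.71e-19 in RVT_P8 and 0.000314 in RT_P8. With an estimated correlation, p = 0.00425 in RV_P8, p = 0.00134 in RVT_P8 and p = 0.0848 in RT_P8.

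**Figure D2:**
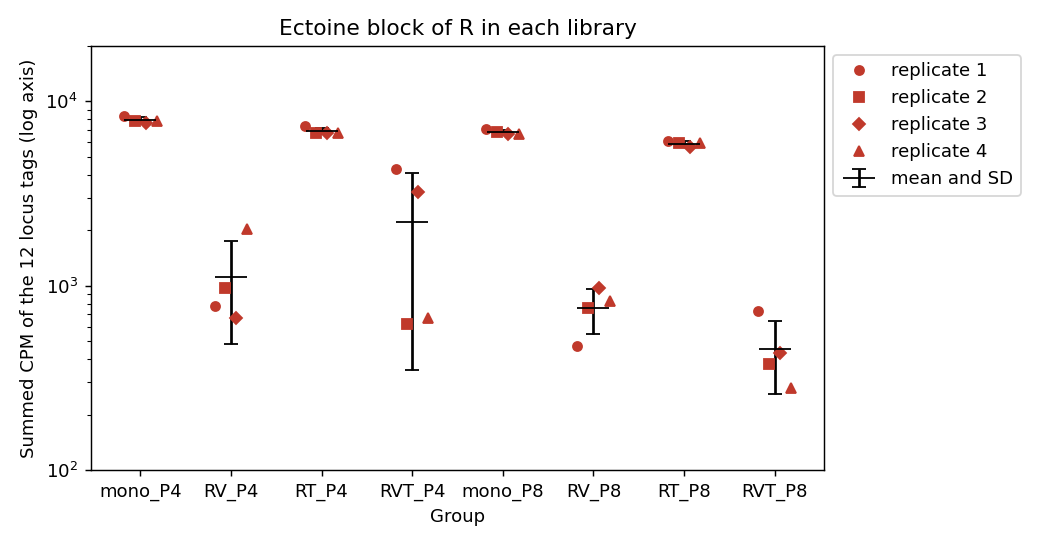
Summed CPM of the 12 locus tags SPO1137 to SPO1148 of R in each library (log axis), by group, with the mean and SD of 4 libraries. Monoculture and RT libraries sat between 5638 and 8345 CPM, and every RV and RVT library lay below them, the highest being RVT_P4 replicate 1 at 4321.

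Among single tags of R at P8, SPO1559 rose from 0.352 ± 0.246 to 133 ± 62.1 CPM in RV_P8 and SPO3498 from 15.7 ± 3.77 to 2209 ± 764, with adjusted p of 7e-11 and 4.32e-14 (edgeR). SPO1146 and SPO1143 of the ectoine block had no read in the 4 RV_P8 libraries, against 458 ± 74.8 and 203 ± 45.8 CPM in mono_P8, which makes them at least 36.8-fold and 16.3-fold lower against a floor of 3 reads over the group. SPOA0189 rose in RT_P8 to 184 ± 55.7 CPM from 15.6 ± 4.195, and SPO3498 to 183 ± 66.4 from 15.7 ± 3.77. The neighbours SPO1789 and SPO1790 fell in RT_P8, with log2 fold changes of −4.68 (SE 0.32) and −4.55 (SE 0.34). In RVT_P8, SPO2192 rose from 11.6 ± 2.39 to 7963 ± 8252 CPM and SPOA0407 from 22.5 ± 5.07 to 4732 ± 2298. The log2 fold change of SPO2192, 9.38 with all libraries, ran from 8.44 (without RVT_P8 replicate 2) to 9.72 over fits without 1 library. SPO1143 and SPO1018 had no read in RVT_P8 and were at least 31.1-fold and 12.6-fold lower than in mono_P8. The RT_P8 count was 290 without mono_P8 replicate 2 and 319, 325, 335 and 363 without RT_P8 replicates 1 to 4. Without composition scaling the splits were 272 up and 2325 down in RV_P8, 185 and 404 in RT_P8, and 441 and 1782 in RVT_P8, so the balance of rises and falls in R at P8 holds only relative to the bulk of its genes.

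At P4, of 3931 genes of V tested, 545 rose and 878 fell in RV_P4 against mono_P4, 369 rose and 365 fell in VT_P4, and 176 rose and 144 fell in RVT_P4 (edgeR, adjusted p under 0.05). V had far fewer reads in VT_P4 than in RV_P4, and after thinning to equal depth the counts were 553 in RV_P4, 429 in VT_P4 and 104 in RVT_P4. The neighbours Vibrio_sp_HF70.CDS.1710 and Vibrio_sp_HF70.CDS.1711, within a run of 7 consecutive tags that rose, went from 39.0 ± 14.8 and 33.1 ± 12.8 CPM in mono_P4 to 1324 ± 123 and 716 ± 65.4 in RV_P4. Vibrio_sp_HF70.CDS.2240 and Vibrio_sp_HF70.CDS.4298 fell in RV_P4, with log2 fold changes of −5.24 (SE 0.60) and −5.09 (SE 0.40). In VT_P4, Vibrio_sp_HF70.CDS.4354, in a run of 8 tags that rose, went from 0.991 ± 0.878 to 48.7 ± 22.3 CPM and Vibrio_sp_HF70.CDS.4416 from 7.28 ± 1.21 to 332 ± 117. The log2 fold change of Vibrio_sp_HF70.CDS.4354 was 5.70, and ran from 5.15 to 6.41 (without mono_P4 replicate 1) over fits without 1 library. Vibrio_sp_HF70.CDS.3360 and Vibrio_sp_HF70.CDS.394 had 1 read each in the 4 VT_P4 libraries, against 136 ± 82.4 and 77.3 ± 42.2 CPM in mono_P4, so their ratios of mono to VT lay between 13.0 and 2858 and between 7.36 and 1620 by counting error. In RVT_P4, Vibrio_sp_HF70.CDS.2184 rose from 71.8 ± 37.7 to 1513 ± 1437 CPM and Vibrio_sp_HF70.CDS.1555 from 667 ± 473 to 10375 ± 9803. Vibrio_sp_HF70.CDS.1219, with 2 reads in RVT_P4 and a ratio of mono to RVT between 8.71 and 260, and its neighbour Vibrio_sp_HF70.CDS.1220, with a log2 fold change of −4.31 (SE 0.87), fell in RVT_P4. With the 2 groups alone in the fit, 10 genes were called, and Vibrio_sp_HF70.CDS.2184, Vibrio_sp_HF70.CDS.1555 and Vibrio_sp_HF70.CDS.1220 had adjusted p of 0.0587, 0.116 and 0.123 (edgeR). Vibrio_sp_HF70.CDS.1220 was at −2.90 without mono_P4 replicate 1, and Vibrio_sp_HF70.CDS.1219 missed 0.05 in 3 of the 5 fits without 1 library that tested it.

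The RVT_P4 count of 320 for V was 10 with those 2 groups alone in the fit, 1047 without RVT_P4 replicate 1, 165, 181 and 136 without replicates 2 to 4, and 202 without mono_P4 replicate 3. The RV_P4 count of 1423 was 927 without RV_P4 replicate 3 and 929 and 930 without mono_P4 replicates 3 and 4. The split without composition scaling was 306 up and 1576 down in RV_P4 and 122 up and 199 down in RVT_P4.

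At P8, of 3725 genes of V tested, 6 rose and 2 fell in RV_P8 against mono_P8, 108 rose and 67 fell in VT_P8, and 698 rose and 559 fell in RVT_P8 (edgeR, adjusted p under 0.05). The neighbours Vibrio_sp_HF70.CDS.2544 and Vibrio_sp_HF70.CDS.2545 rose in RV_P8 from 277 ± 82.8 to 965 ± 187 CPM and from 2245 ± 359 to 6684 ± 2127. Vibrio_sp_HF70.CDS.2834 and Vibrio_sp_HF70.CDS.3695 fell there, with log2 fold changes of −1.94 (SE 0.34) and −1.57 (SE 0.31). The second missed 0.05 under 5 alternatives, with adjusted p from 0.0533 without a filter on low counts to 0.461 after thinning, and both tags missed it in 7 of 8 fits without 1 library. In a run of 3 neighbours that rose in VT_P8, Vibrio_sp_HF70.CDS.482 and Vibrio_sp_HF70.CDS.483 stood at 9106 ± 14764 and 49717 ± 80360 CPM there, against 22.9 ± 9.89 and 72.4 ± 62.6 in mono_P8. VT_P8 replicate 3 alone reached 31168 and 169752 CPM for this pair, and without it their log2 fold changes were 6.26 and 7.004 in place of 8.64 and 9.38. In RVT_P8, Vibrio_sp_HF70.CDS.482 was at 763 ± 1335 CPM and Vibrio_sp_HF70.CDS.481 at 196 ± 313, against 6.31 ± 2.90 for the latter in mono_P8, and RVT_P8 replicate 3 held the highest values, 2761 and 664 CPM. Without that library neither passed the test: Vibrio_sp_HF70.CDS.482 went from a log2 fold change of 5.08 to 2.15 (adjusted p = 0.140) and Vibrio_sp_HF70.CDS.481 from 4.93 to 2.65 (adjusted p = 0.115). In the authors' 3-replicate table Vibrio_sp_HF70.CDS.482 was at 2.01 (adjusted p = 0.0653). Vibrio_sp_HF70.CDS.4248 to Vibrio_sp_HF70.CDS.4251 lay in a run of 9 tags that fell in both VT_P8 and RVT_P8: Vibrio_sp_HF70.CDS.4248 fell by 3.38 (SE 0.47) in VT_P8, and Vibrio_sp_HF70.CDS.4250 and Vibrio_sp_HF70.CDS.4251 had log2 fold changes of −4.25 (SE 0.56) and −4.47 (SE 0.69) in RVT_P8. All reads of these 2 tags in RVT_P8 came from replicate 3, so the size of both falls rests on that library, and Vibrio_sp_HF70.CDS.4248 was at −4.34 without VT_P8 replicate 3. Vibrio_sp_HF70.CDS.1710 fell in VT_P8 (log2 fold change −3.14, SE 0.37), from 921 ± 158 to 102 ± 64.9 CPM.

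The VT_P8 count of 175 for V was 889 without VT_P8 replicate 3, 97 and 92 without replicates 1 and 4, and 76, 79 and 83 without mono_P8 replicates 2 to 4. The RVT_P8 count was 830 without mono_P8 replicate 2, and the RV_P8 count was 5 without mono_P8 replicate 1 or 4 and without RV_P8 replicate 3 or 4. With the 2 compared groups alone in the fit, RV_P8 had 154 genes and VT_P8 63, so the order of these 2 groups depends on the fit. The RVT_P8 split without composition scaling was 1021 up and 278 down.

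**Figure D3:**
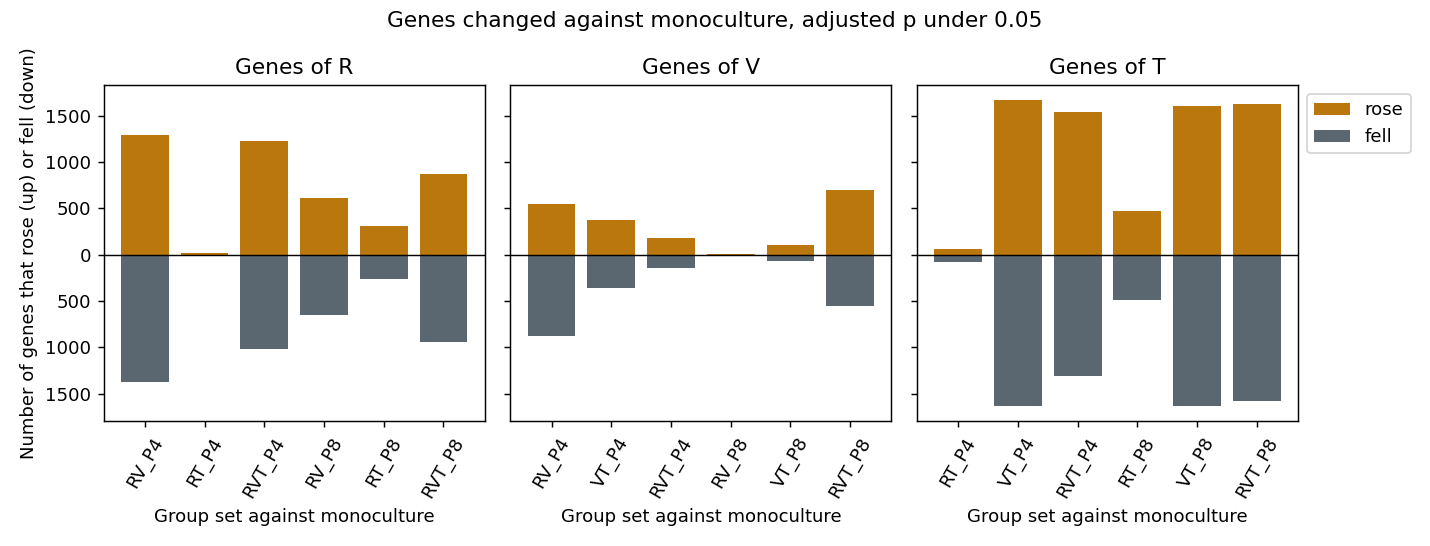
Number of genes of R, V and T that rose (bars upward) or fell (bars downward) in each group against monoculture at the same time point, adjusted p under 0.05. In T, VT and RVT bars reach 1312 to 1666 genes each way, against 56 to 494 in RT. With the compared groups alone in the fit, the contrast of RVT_P4 with RT_P4 in T was small (1472 and 1427 genes).

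More genes of T changed beside V than beside R alone. At P4, of 3878 genes tested, 1666 rose and 1631 fell in VT_P4 against mono_P4, 1538 rose and 1312 fell in RVT_P4, and 56 rose and 81 fell in RT_P4 (edgeR, adjusted p under 0.05). A run of 27 consecutive tags of T rose in VT_P4. Within it, Tha15_02546 and Tha15_02548 went from 5.86 ± 1.67 and 1.80 ± 0.604 CPM in mono_P4 to 8041 ± 989 and 2960 ± 233 in VT_P4, with adjusted p of 1.28e-05 and 2.88e-05 (edgeR). Tha15_00365 fell in VT_P4 from 328 ± 15.5 to 1.20 ± 1.11 CPM. Its log2 fold change was −8.11, and ran from −8.96 (without VT_P4 replicate 4) to −7.76 over fits without 1 library. Tha15_00703, with 2 reads left in 4 libraries, had a ratio of mono to VT between 81.8 and 2439. In RVT_P4, Tha15_03094 and Tha15_03095, in a run of 10, rose from 12.5 ± 2.01 and 9.84 ± 3.16 to 3803 ± 3861 and 3058 ± 3179 CPM. Their log2 fold changes were 8.25 and 8.27. Without 1 library they ran from 7.74 to 8.65 and from 7.65 to 8.67, both lowest without RVT_P4 replicate 4. Tha15_03929 and Tha15_01123 fell in RVT_P4, with log2 fold changes of −7.62 (SE 0.89) and −5.23 (SE 0.21). The same 2 tags fell in RT_P4, with −3.63 (SE 0.70) and −5.75 (SE 0.21). Tha15_03929 was at 272 CPM in mono_P4 replicate 1 and at 36.6 to 40.3 in the other 3, and without replicate 1 its log2 fold changes were −6.31 in RVT_P4 and −2.32 in RT_P4. Without RVT_P4 replicate 1 it was at −8.99 in RVT_P4. Tha15_01508 and Tha15_01510, in a run of 6, rose in RT_P4 from 163 ± 28.2 and 171 ± 37.3 to 1478 ± 107 and 1372 ± 88.8 CPM.

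RVT_P4 replicate 1 stayed close to monoculture in T. On a scale where 0 is the mono mean of the same time and 1 the limited VT change of the other time, it stood at 0.12. The other 3 RVT_P4 libraries stood at 0.84 to 1.03, VT_P4 at 1.11 to 1.13 and RT_P4 at 0.02 to 0.04. RVT_P4 replicate 1 was also the lowest of the 4 in R, at 0.23 along the RV change against 0.44 to 0.58. The same held in V, at 0.20 along the VT change against 0.34 to 0.46. Without it the RVT_P4 count in T was 3344 in place of 2850. The RT_P4 count of 137 was 87, 84, 81 and 76 without RT_P4 replicates 1 to 4 and 88, 90 and 74 without mono_P4 replicates 1 to 3. With the 2 compared groups alone in the fit, 1427 genes changed in RT_P4, 1472 in RVT_P4 (1127 up and 345 down) and 3454 in VT_P4, so at P4 the contrast with RT holds in that fit for VT and is small for RVT. The VT_P4 split without composition scaling was 1243 up and 1993 down.

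At P8, of 3898 genes of T tested, 1602 rose and 1634 fell in VT_P8 against mono_P8, 1624 rose and 1584 fell in RVT_P8, and 471 rose and 494 fell in RT_P8 (edgeR, adjusted p under 0.05). Tha15_02546 and Tha15_02548, now in a run of 31 tags that rose, went from 5.14 ± 1.82 and 2.16 ± 1.07 CPM in mono_P8 to 5183 ± 4726 and 1445 ± 1221 in VT_P8. Their log2 fold changes were 9.98 and 9.38. Without 1 library they ran from 9.16 to 10.39 and from 8.70 to 9.80, both lowest without VT_P8 replicate 4. Tha15_01868 and Tha15_02500 fell in VT_P8, with log2 fold changes of −7.40 (SE 0.51) and −7.21 (SE 0.41). In RVT_P8, Tha15_02548 rose to 584 ± 514 CPM and Tha15_03095 from 18.5 ± 14.9 to 4774 ± 990. The log2 fold changes were 8.07 and 8.02. Without 1 library they ran from 7.48 (RVT_P8 replicate 2) to 8.45 and from 7.82 to 8.76 (mono_P8 replicate 2). Tha15_03929 and Tha15_01326 fell in RVT_P8, with log2 fold changes of −7.90 (SE 0.58) and −7.63 (SE 0.50), the second at −8.44 without RVT_P8 replicate 1. In RT_P8, Tha15_02223 and Tha15_02068 rose from 80.3 ± 7.09 and 10.9 ± 3.11 to 1007 ± 88.4 and 133 ± 25.4 CPM. The neighbours Tha15_01377 and Tha15_01378 fell in RT_P8 from 3627 ± 210 and 3115 ± 159 to 35.1 ± 3.47 and 15.1 ± 1.61 CPM. With the 2 compared groups alone in the fit, 2510 genes changed in RT_P8, 3248 in VT_P8 and 3161 in RVT_P8.

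**Figure D4:**
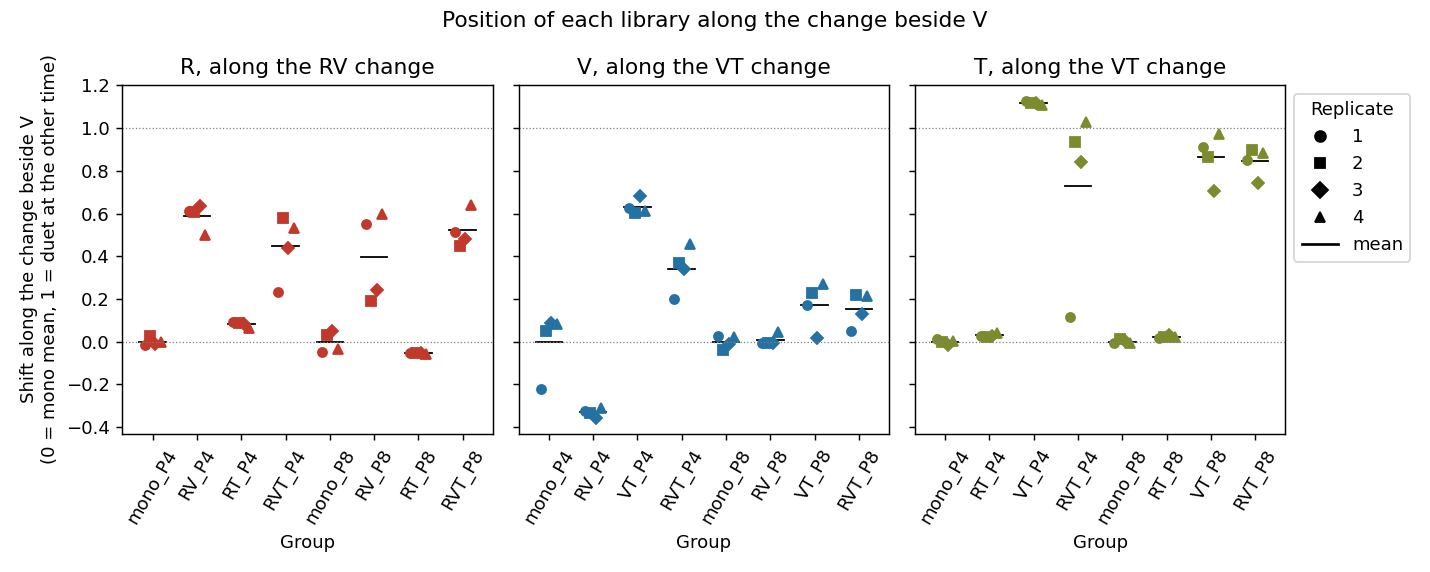
Position of each library (points, shaped by replicate) and group mean (line) along the change that R showed in RV, and V and T in VT, at the other time point, where 0 is the mono mean and 1 the full change. T stood at 0.02 to 0.04 in RT and at 0.70 to 1.13 in VT, and RVT_P4 replicate 1 at 0.12.

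Adding the remaining species to a pair went with fewer changed genes in R and T where V was already present than where it was not. In R, 438 genes rose and 289 fell in RVT_P4 against RV_P4, and 1277 rose and 937 fell against RT_P4. At P8 the corresponding numbers were 187 and 248 against RV_P8 and 942 and 992 against RT_P8 (edgeR, adjusted p under 0.05). The P8 pairs differ in depth, with a mean of 97503 reads of R in RV_P8 and 745040 in RT_P8. After thinning to equal depth, the count against RT_P8 was 823 in place of 1934. The count of 435 against RV_P8 stayed within 1.5 times. In T, 1021 rose and 538 fell in RVT_P4 against VT_P4 and 1513 rose and 1345 fell against RT_P4, and at P8 100 rose and 132 fell against VT_P8 and 1626 rose and 1584 fell against RT_P8. The balance in T against VT depends on the fit: with the compared groups alone, 14 rose and 80 fell against VT_P4 and 0 rose and 10 fell against VT_P8, and with the replicate number as a block 523 rose and 461 fell against VT_P4. The ectoine block of R fell in the trio against RT, with 6 of 12 tags at P4 (median log2 fold change −1.26, camera p = 0.000824, and p = 0.278 with an estimated correlation) and 12 of 12 at P8 (median −3.77, also with the 1 tag without a read at its floor, p = 1.88e-14, and p = 0.00287 with an estimated correlation). Against RV_P4, 4 tags of the block rose (median 1.65), with camera p = 0.0687, p = 0.557 with an estimated correlation and p = 0.204 with fry. Over all alternatives this p ran from 0.00238 without RVT_P4 replicate 4 to 0.740 without RVT_P4 replicate 1. Against RV_P8, 1 tag fell. At P8 the block's median log2 fold change was 0.999, or 0.85 with SPO1143, which had no read in either group, left out and SPO1146, which had none in RV_P8, placed at the floor of 3 reads over the group, while the summed level was lower in RVT, 453 ± 193 against 757 ± 209 CPM. The camera test there pointed down, with adjusted p = 0.888. Adjusted over the list alone, these counts were 6, 12, 4 and 1.

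V followed another order. Its genes differed between RVT_P4 and RV_P4 in 342 rises and 194 falls and between RVT_P4 and VT_P4 in 15 rises and 31 falls. These counts are not at like depth, as V had a mean of 126448 reads in VT_P4 and 2612944 in RV_P4. After thinning to equal depth, 170 genes were called against RV_P4 and 24 against VT_P4. At P8, 548 rose and 381 fell against RV_P8, and 0 rose and 4 fell against VT_P8 (edgeR, adjusted p under 0.05), where 649 genes had an unadjusted p under 0.05 and DESeq2 called 39, of which 10 rose. The V count against VT_P8 was 14 without RVT_P8 replicate 3, 9 and 2 without VT_P8 replicates 1 and 2. Against VT_P4 it was 28, 22 and 26 without VT_P4 replicates 1, 3 and 4 and 16 without RVT_P4 replicate 3. The V count of 536 against RV_P4 was 349, 295, 320 and 356 without RV_P4 replicates 1 to 4, and that of 929 against RV_P8 was 582 and 586 without RV_P8 replicates 2 and 3 and 567 without RVT_P8 replicate 2. For T, the count of 1559 against VT_P4 was 986, 1000, 1027 and 1023 without VT_P4 replicates 1 to 4, and that of 232 against VT_P8 was 550 and 126 without VT_P8 replicates 3 and 2 and 349 without RVT_P8 replicate 3. For R, the count of 727 against RV_P4 was 460 and 467 without RV_P4 replicates 1 and 3 and 470 without RVT_P4 replicate 3. Its split of 60.2% rises was 49.5% with DESeq2 size factors, and 38% with the top 1 percent of genes left out.

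Without composition scaling, the trio's splits in R were 251 up and 458 down against RV_P4, 927 and 1322 against RT_P4, 729 and 169 against RV_P8, and 534 and 1569 against RT_P8. In V they were 656 and 104 against RV_P4 and 794 and 180 against RV_P8, and in T 1709 and 329 against VT_P4. The median log2 fold change of all genes of R in RV_P8 moved by −1.19 and that in RVT_P8 against mono_P8 by −0.68 under this scaling, and that of T in VT_P4 by −0.65, so the changes reported here are relative to the bulk of each species' genes.

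The trio's change against monoculture differed between time points in 317 of 3630 genes of R, 495 of 3876 of V and 96 of 3899 of T, by the interaction of condition and time (edgeR, adjusted p under 0.05). Called at both time points in the same direction were 1315 genes of R, 139 of V and 2834 of T. In R the ectoine block fell further at P8, by a median of −2.37 on the log2 scale, also with the 1 tag without a read at its floor (camera p = 2.8e-06, and p = 0.113 with an estimated correlation), with 3 of 12 tags past the test over all genes and 11 adjusted over the list alone. In summed level this rests on RVT_P4 replicates 1 and 3, at 4321 and 3235 CPM. RVT_P4 replicates 2 and 4, at 622 and 671 CPM, lay within the RVT_P8 range of 278 to 727. SPO1172 fell less at P8 (difference 2.54, SE 0.79), which missed 0.05 in 10 of 16 fits without 1 library. In V, Vibrio_sp_HF70.CDS.1555 rose at P4 and stood at a log2 fold change of 0.28 at P8, and Vibrio_sp_HF70.CDS.482 stood at −0.55 at P4 and rose at P8, a rise that rests on RVT_P8 replicate 3, without which the difference was 2.69 in place of 5.63 (adjusted p = 0.1201). In T, Tha15_01326 had log2 fold changes of −3.29 at P4 and −7.60 at P8, a difference of −4.31 that was −1.23 without RVT_P4 replicate 1 (adjusted p = 0.438). The R count was 972 without RVT_P4 replicate 1, 191 without RVT_P4 replicate 3 and 196 without RVT_P8 replicate 4. The V count was 1288 without RVT_P4 replicate 1, 324, 329 and 317 without RVT_P4 replicates 2 to 4, 795, 792 and 313 without mono_P4 replicates 1, 2 and 4, and 325 without mono_P8 replicate 2. The T count was 364, 349 and 502 without RVT_P4 replicates 2 to 4, 279, 56 and 55 without RVT_P8 replicates 1, 2 and 4, 63, 61 and 62 without mono_P4 replicates 2 to 4, and 59, 55 and 60 without mono_P8 replicates 1, 3 and 4. Without composition scaling the numbers higher and lower at P8 were 75 and 565 in R in place of 158 and 159, and 669 and 94 in V in place of 292 and 203. With DESeq2 size factors they were 140 and 213 in R, and with the compared groups alone 43 and 13.

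Changed genes lay side by side in the numbering of the locus tags. The levels of adjacent tags correlated across libraries with a median r of 0.26 (V at P8) to 0.78 (T at P4), across genes, which are not independent replicates, against −0.03 to 0.04 for random pairs. In R, 73.9% of the genes changed in RV_P4 had an adjacent tag changed in the same direction, against 55.02% on average when the calls and their directions were shuffled over tags. In V the share in RV_P4 was 50.4% against 32.1%, and in T it was 83.6% in VT_P4 against 66.2%. Each had permutation p = 0.001, the smallest that 1000 shuffles can give. Against monoculture, the longest runs in T were 47 tags that fell, in VT_P8 and in RVT_P8, and 31 that rose, in these 2 and in RVT_P4, and the longest in R was 28 tags that rose in RVT_P4. In V the longest was 13 tags that fell in RVT_P8.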

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

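The tests of depth, of reads of V counted as R, of RVT_P4 replicate 1, of the relations across P8 libraries and of other splits of the samples were chosen after the results were seen, and those of reads of V counted as T before.

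Most genes of T in VT_P4 and of R in RV_P4 changed. Depth is argued against at P4: with all libraries thinned to equal depth, 3163 genes were called in T in VT_P4 (3297 as deposited) and 1936 in R in RV_P4 (2668 as deposited). Reads of V counted as T are argued against. Genes that fell in VT_P4 had a median log2 fold change of −0.0118 in RT_P4 (quartiles −0.19 and 0.18), which holds no V, against −2.19 in VT_P4. The reads added to genes that rose were 19.4 times the reads assigned to V genes there (9837257 against 505794). That total leaves out any V reads counted as T, so miscounting would have to take most V reads. If V gave all reads of the genes that rose in R in RV_P4, they would stand 5.63-fold higher in mono_P4 replicate 4 than in replicate 1. The median over 1293 genes was 0.994 (quartiles 0.837 and 1.19). A smaller part of reads from V would raise them less, and no expected value was set for that. In R at P8 thinning left 617 calls of 1267, but also 1398 genes to test of 3330. Among the genes tested both ways, 770 were called as deposited and 617 after thinning, 588 of them in both, which is 80.1% as many (75.9% to 83.0% over 20 draws), so a difference in depth is argued against for these. Of the 497 called genes too low to test at equal depth, 32.4% were called without a filter (30.1% to 36.7% over the draws), and the calls ended with the reads, not with the fold: the size of the median log2 change was 1.64 as deposited (quartiles 1.24 and 2.38) and 1.62 after thinning (1.05 and 2.42), at a median of 6 reads per gene over the 4 RV_P8 libraries. The lost calls therefore do not count for depth, but as thinning leaves a fold the same on average, they do not count against it either, and for these genes depth and a response to V cannot be told apart. A response to V stays open as a hypothesis.

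RVT_P4 replicate 1 stood near monoculture in T, with a shift of 0.12 against 0.84 to 1.03 in the other 3 libraries. This library was also the lowest of the 4 in R (0.23 against 0.44 to 0.58) and in V (0.20 against 0.34 to 0.46). It did not lack V, which held 7.19% of its reads, against 5.27% to 7.10% in the others. A mixture with mostly reads of a library without V would lower this share, which was not below the others, and so is argued against. Scaling the V share with the T shift gave 0.760%. That value is rough, since reads mix as counts and the shift is on the log2 scale. Its T reads, 6533427, exceeded those of every VT_P4 library (at most 4167215), which argues against low depth. An earlier or slower culture may give this and stays open, as nothing in the labels tests it.

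Across the 8 VT_P8 and RVT_P8 libraries, chosen after their values were seen, the shift of T went with that of V (Pearson r 0.790, exact permutation p = 0.0235, adjusted 0.0235, Spearman rho 0.762, p = 0.0368, adjusted 0.0735 over 2 relations). Without VT_P8 replicate 3 and RVT_P8 replicate 1, r was 0.832, and centred within each group it was 0.787. With the share of V reads, r was −0.851 (exact permutation p = 0.00945, adjusted 0.0189) and rho −0.524 (p = 0.197, adjusted 0.197). This relation rests on VT_P8 replicate 3 and RVT_P8 replicate 3, without which r was −0.004, and centred within each group it was −0.963. The permutation test takes the 8 libraries as independent, which the labels do not state. Whether T may follow the state or the share of V cannot be told apart in these data, since groups of 4 are too few for a relation within a group.

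Single libraries far from the other 3 of their group were found in 28 of 192 groups of values tested. Chance flags about 1 in 20 groups, or 9.6, only where values are independent and normally spread. Many values here are CPM of tags chosen for large changes, and some groups had reads in 1 library only. The number above 9.6 is therefore not read as an excess. In shares and totals, T held 87.6% of reads in RT_P4 replicate 4 (others 91.3 to 91.9), V held 90.6% in RV_P8 replicate 4 (94.2 to 94.8), and VT_P4 replicate 1 had 4284126 reads (3244433 to 3406217). The shift of V was −0.22 in mono_P4 replicate 1 (0.05 to 0.09) and 0.0444 in RV_P8 replicate 4 (−0.00837 to −0.00477), and the ectoine block stood at 7317 CPM in RT_P4 replicate 1 (6753 to 6767).

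Among named tags of R, SPO2195 stood at 180 CPM in RV_P4 replicate 4 (14.8 to 38.6), SPO1172 at 136 in mono_P4 replicate 2 (344 to 368), SPO1177 at 36.9 in RVT_P4 replicate 1 (5.08 to 7.78) and 389 in mono_P4 replicate 1 (64.5 to 81.3), and SPOA0189 at 100.2 in RT_P8 replicate 4 (207 to 217). Among those of T, Tha15_03929 stood at 272 in mono_P4 replicate 1 (36.6 to 40.3) and 1.52 in RVT_P4 replicate 1 (0.130 to 0.192), Tha15_02223 at 1140 in RT_P8 replicate 4 (961 to 965), Tha15_01868 at 7.63 in VT_P8 replicate 3 (3.49 to 4.12) and Tha15_03095 at 40.9 in mono_P8 replicate 2 (10.6 to 11.4).

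Among those of V at P4, Vibrio_sp_HF70.CDS.1711 stood at 618 CPM in RV_P4 replicate 1 (737 to 757), Vibrio_sp_HF70.CDS.3360 at 5.70 in VT_P4 replicate 4 and Vibrio_sp_HF70.CDS.394 at 8.08 in VT_P4 replicate 1 (0 in the others), Vibrio_sp_HF70.CDS.2184 at 3665 in RVT_P4 replicate 1 (726 to 901) and Vibrio_sp_HF70.CDS.1220 at 149 in mono_P4 replicate 1 (14.8 to 23.9). At P8, Vibrio_sp_HF70.CDS.483 stood at 169752 in VT_P8 replicate 3 (1467 to 19301) and 166 in mono_P8 replicate 4 (39.4 to 42.1), and Vibrio_sp_HF70.CDS.482 at 31168 in VT_P8 replicate 3 (337 to 3432). RVT_P8 replicate 3 held 2761 CPM of Vibrio_sp_HF70.CDS.482 (34.8 to 218), 664 of Vibrio_sp_HF70.CDS.481 (21.4 to 68.0), 3.01 of Vibrio_sp_HF70.CDS.4251 and 7.02 of Vibrio_sp_HF70.CDS.4250 (0 in the others).

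The trio's change against monoculture differed between time points, by the interaction test, in 317 genes of R, 495 of V and 96 of T. Among named tags the log2 difference, P8 minus P4, was 2.54 for SPO1172, −9.34 for SPO1143, −8.78 for SPO1018, −3.68 for Vibrio_sp_HF70.CDS.1555, 5.63 for Vibrio_sp_HF70.CDS.482, 4.36 for Vibrio_sp_HF70.CDS.481 and −4.31 for Tha15_01326. Without RVT_P8 replicate 3 it was 2.69 for Vibrio_sp_HF70.CDS.482 and 2.09 for Vibrio_sp_HF70.CDS.481, and without RVT_P4 replicate 1 it was −1.23 for Tha15_01326, none of which passed the test (adjusted p of 0.1201, 0.237 and 0.438). Of 16 fits without 1 library, SPO1172 and SPO1018 missed 0.05 in 10 each, Vibrio_sp_HF70.CDS.481 in 10 and Tha15_01326 in 11. SPO1143 and SPO1018 had no read in RVT_P8, so their fitted differences depend on the prior count and are no bounds. Outside the comparisons, the 10 foot rows with no gene name in the P4 table of V held up to 67.9% of a column's sum.

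Other splits of the samples were refitted with the compared groups alone. For 27 of the 30 comparisons, 1 of 35 splits, the real one, gave as many genes. A share of 1 in 35 is the smallest these splits can give, and it is not adjusted over the 30 comparisons. A mixed split also carries the real difference as spread, which lowers its count. The real split thus ranked first, but this does not exclude chance. The counts of these fits can differ from those reported, as with 94 against 1559 in T, RVT_P4 against VT_P4. The highest other split had 888 genes against 1472 in T, RVT_P4 against mono_P4, 565 against 1644 in T, RVT_P4 against RT_P4, and 0 or 1 in the rest of these. For V the real split did not stand alone in RVT_P4 against mono_P4 (3 of 35 splits, real 10, highest other 497). The same held in VT_P8 against mono_P8 (2 of 35, 63 and 589) and RVT_P8 against VT_P8 (3 of 35, 1 and 3), and chance is not excluded in any of these. The splits with 497 and 589 genes point to a structure in the samples: the first groups RVT_P4 replicate 1 with 3 mono libraries, the second VT_P8 replicate 3 with mono. For the time differences, 5 of 60 splits in R (real 56, highest other 2369), 6 of 60 in V (93 and 581) and 5 of 60 in T (21 and 3217) gave as many genes. Chance is not excluded there, and exchanging labels at 1 time point turns the shared change of the trio into a difference.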

How the results depend on the processing

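The alternative without composition scaling was chosen after the data were seen, and the others before the data were examined. Counts stayed within 1.5 times of the reported one in 33 of 33 results with DESeq2 size factors and without a filter on low counts, in 32 with the top 1 percent of genes left out, in 29 with the replicate number as a block, in 28 without composition scaling, in 22 with the DESeq2 Wald test, in 19 after thinning and in 14 with the compared groups alone. With the authors' 3-replicate tables they did in 9 of 12. The direction of each named tag was the same under the alternatives run, those without 1 library included. On average, replicate numbers did not pair the samples: the mean correlation of residuals between libraries of like number was −0.0637 to 0.0697. A library's own number gave the best match in 5 or 6 of 24 pairs. Single pairs of like number ran from −0.757 (V at P4) to 0.690 (T at P8), so a shared origin of some pairs is not excluded. The block is given as an alternative only.

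With the DESeq2 Wald test, 11 counts were higher: in R, RT_P4 against mono 85, RT_P8 against mono 966 and the time difference 544; in V, RVT_P4 against mono 595, against RV 808 and against VT 128, and at P8 RV against mono 23, VT against mono 297 and RVT against VT 39; in T, RT_P4 against mono 291 and RVT_P8 against VT 401. With the replicate block, R in RT_P4 had 15, V in RVT_P4 150 against mono and 21 against VT, and T in RVT_P4 984 against VT. Thinning, which leaves fewer genes to test, gave in R 5 in RT_P4, 407 in RVT_P4 against RV, 617 in RV_P8, 66 in RT_P8, 781 in RVT_P8 against mono, 823 in RVT_P8 against RT and 72 for the time difference. In V it gave 553 in RV_P4, 429 in VT_P4, 104 in RVT_P4 against mono, 170 against RV, 24 against VT, 0 in RVT_P8 against VT and 167 for the time difference.

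Without composition scaling, R had 2597 in RV_P8, 898 in RVT_P8 against RV and 640 for the time difference, and V had 0 in RVT_P8 against VT and 763 for the time difference. With the compared groups alone, where 5 counts were higher and 14 lower, R had 290 in RT_P4, 124 in RVT_P4 against RV, 975 in RT_P8, 283 in RVT_P8 against RV and 56 for the time difference. V had 383 in VT_P4, 10 in RVT_P4 against mono, 14 against VT, 154 in RV_P8, 63 in VT_P8, 1 in RVT_P8 against VT and 93 for the time difference. T had 1427 in RT_P4, 1472 in RVT_P4 against mono, 1644 against RT, 94 against VT, 2510 in RT_P8, 10 in RVT_P8 against VT and 21 for the time difference. The top 1 percent left out gave V 5 in RV_P8. The authors' 3-replicate tables gave R 266 in RT_P8 and 150 for the time difference, and V 915 in VT_P8. The table for V leaves out VT_P8 replicate 3 among others, and without that library alone the VT_P8 count was 889. Why the other counts moved was not tested.

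With medians in place of means, the exact permutation p became 0.0571 for 7 tests whose smallest possible p was met with means. The differences were 7.25 points for V in RV, 11.9 for V in VT and −1.45 for R in RVT, and on the log2 scale −1.24 for V to R in RVT_P4, 1.06 for V to T in RVT_P4, and 1.80 and 3.21 for T to R in RVT_P4 and RVT_P8.

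Leaving out each library in turn gave these ranges. In R: RT_P4 8 to 22, RVT_P4 against RV 460 to 1029, RT_P8 290 to 645, the time difference 191 to 972. In V: RV_P4 927 to 1692, RVT_P4 against mono 136 to 1047, against RV 295 to 504, against VT 16 to 45, RV_P8 5 to 9, VT_P8 76 to 889, RVT_P8 against mono 830 to 1375, against RV 567 to 1105, against VT 2 to 14, the time difference 313 to 1288. In T: RT_P4 74 to 137, RVT_P4 against VT 986 to 1962, RVT_P8 against VT 126 to 550, the time difference 55 to 502. The floor of 3 reads was highest for R in RVT_P8, at 54.9 CPM in 1 library, while the simulated recovery of changes of 4-fold was lowest for V in VT_P4, at 59.1%.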

Other observations

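The test of tags with prefix SPOA was chosen after the data were seen. These tags, numbered apart from the SPO series of R, rose more often than the SPO tags in RV_P4: of 258 tested, 136 rose and 66 fell (median log2 fold change 0.79), against 1157 and 1309 of 3267 SPO tags (median −0.11). The camera adjusted p was 0.00118 over 10 comparisons, and p = 0.0906 with an estimated correlation. In RVT_P4 against RV_P4, 10 SPOA tags rose and 32 fell (median −0.15), with adjusted p = 0.000973 and p = 0.0673 with an estimated correlation. In the other 8 comparisons the adjusted p was 0.0725 or more.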
